A study of Homo sapiens with 9 samples.

How the data were processed

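Expression was measured in 9 samples on Affymetrix HuGeneFL arrays: 3 samples of leukemic blasts from patients with acute myeloid leukemia (AML), 3 of neutrophils and 3 of monocytes from normal blood, the latter groups isolated on a density gradient, per the labels. The groups were taken from the sample titles and descriptions. The table deposited by the authors holds 1 intensity per probe set and array on a linear scale, as whole numbers with many values below 0. RNA extraction, labelling and hybridization follow a cited protocol, per the labels, and the software and the scaling of the intensities are not given in the sources used here. No other kind of file was used.

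The array holds 7129 probe sets. Genes were named from GEO's platform annotation, which gives 1 gene symbol for 5709 probe sets, several for 321 and none for 1099. Of the probe sets with 1 symbol, 5704 matched NCBI's RefSeq gene table by gene identifier, and 0 symbols needed an update. The 58 control probe sets and 17 probe sets of genes on the Y chromosome or of the X inactivation transcript were left out of all tests, which left 7054. No gene was named from a probe set with several symbols.

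Trimmed means of the arrays (2% trimmed at each end) differed 9.14-fold, above the limit of 1.1-fold set before the data were examined, so the linear intensities were quantile normalized. Values under 20 were then set to 20, the floor, and log2 was taken. Probe sets with a value over 100 on at least 3 of the 9 arrays were tested, without regard to group, which left 4358 probe sets and 3315 genes. A probe set at the floor on all 3 arrays of a group has only a bound there, and its fold against that group is given as "at least", computed from the floor. Where probe sets of a gene disagreed in direction, the report says so. Other probe sets of named genes gave 58 values, counted per comparison, so a probe set can recur. Of these, 13 had the opposite sign to the named probe set, and 2 were called, both from 1 probe set of ZFP36L1.

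Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on a model of 3 groups fitted to all 9 samples (6 residual degrees of freedom) and no covariates. Each comparison was adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. Calls with the same sign in both comparisons against AML were intersected, beside a simulation of unchanged groups against shared AML arrays (100 simulations). Gene lists fixed before the data were examined (27 lists) were tested with limma's camera on 1 probe set per gene, the one with the highest mean, with a preset correlation of 0.01 and again with an estimated one, and adjusted over 81 tests. Members were also counted after adjustment over the list alone. The macrophage and lysosomal lipid list and the circulating monocyte list were written after the values had been seen, so only counts and medians are given for them. Control probes for the 5' and 3' ends of GAPDH and actin were read from the deposited intensities, and groups were compared by exact two-sided permutation tests. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

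Genes to name were chosen by a rule set before the data were examined. Per comparison it took the 10 genes with the largest difference in each direction among called probe sets with 1 symbol, no overlap between the groups and at least 2 of 3 samples of each group above the floor. It added the 5 genes with the highest mean per direction among called probe sets at the floor on all 3 arrays of the other group, and up to 4 called members of each list with the smallest adjusted p. For the intersection it took 10 genes per direction, and a set of marker genes was given whatever the result. Genes called in opposite directions in the mature groups were added.

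The steps were tested on simulated data with the real arrays' means and spread, in which 200 probe sets were changed, 50 at each fold. These were 200 of 4358 with signs drawn at random, a smaller share than the 14.2% to 21.7% called in the data. Rates in the data may therefore differ, and changes mostly in 1 direction were not simulated. In neutrophils against AML, the fit recovered 2% of probe sets changed 2-fold, 28% at 4-fold, 42% at 8-fold and 58% at 16-fold, and 5.80% of its 69 calls were false. In monocytes against AML it recovered 2%, 34%, 62% and 62%, with 2.44% of 82 calls false, and in neutrophils against monocytes 0%, 30%, 56% and 58%, with 6.49% of 77 calls false.

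Alternatives fixed before the data were examined were no normalization, scaling to a common trimmed mean or 75th percentile, floors of 50 and 100, a ceiling of 16000, no filter or a filter over 200, a variance trend with robust estimation, array quality weights, fits of only the groups compared, the replicate number as a block, genes in place of probe sets, a 2-fold minimum, the mean of a gene's probe sets in the list tests, and each sample left out in turn. The filter kept its minimum of 3 arrays in fits with fewer samples, so a probe set that passed on 3 arrays alone could drop out. Leaving out the 2 dimmest arrays (AML sample 2 and neutrophil sample 3) was added after seeing the data.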

Results

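Expression was measured on 9 Affymetrix HuGeneFL arrays, an early oligonucleotide array with 7129 probe sets, with 1 array per sample. The samples formed 3 groups of 3: leukemic blasts from patients with acute myeloid leukemia (AML), normal neutrophils and normal monocytes. The groups were set against each other to find genes that separate undifferentiated leukemic cells from mature myeloid cells, for use as a differentiation signature in a compound screen. The labels do not say whether the samples of a group came from separate donors, so p-values measure only the spread between these samples, which may be technical. The median deposited intensity of the arrays was 61, 35 and 153 for AML samples 1 to 3, 152, 129 and 28 for neutrophil samples 1 to 3, and 139, 122 and 113 for monocyte samples 1 to 3. The scale of the values and the software that made them are not given in the sources used here. Trimmed means of the arrays differed 9.14-fold, and the arrays were therefore quantile normalized. The number of arrays limits the precision of each difference.

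Arrays of a group resembled each other more than arrays of other groups. Across the 4358 probe sets tested, Pearson's r between arrays ranged from 0.668 to 0.782 within AML, from 0.714 to 0.897 within the neutrophils and from 0.833 to 0.897 within the monocytes. Between groups it ranged from 0.390 to 0.622. These correlations are across probe sets, which are not independent replicates. The first principal component held 35.7% of the variance and the second 25.5%. Differences below are log2 values ± SE from limma's fit (n = 3 per group), with adjusted p over all probe sets tested.

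**Figure D1:**
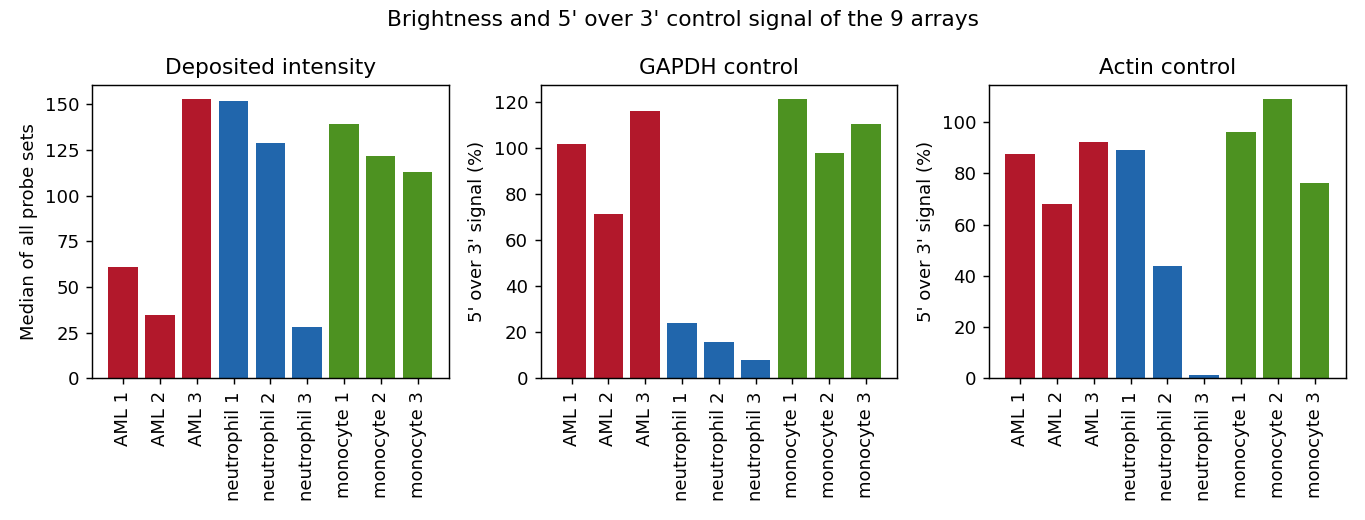
Median deposited intensity of all probe sets, and signal of the GAPDH and actin control probes at the 5' end as a percentage of the 3' end, for each of the 9 arrays (1 bar per array, coloured by group). The neutrophil arrays had the 3 lowest GAPDH percentages, at most 24.3% against at least 71.5% in the other groups, while actin overlapped between the groups (1.27% to 89.3% in neutrophils, 68.0% to 92.2% in AML).

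The first comparison set neutrophils against AML blasts and asked which genes mark the granulocytic end of maturation. The chemokine receptor CXCR2 was higher in neutrophils by 7.23 ± 0.44 (adjusted p = 4.486e-05), the G-CSF receptor CSF3R by 7.10 ± 0.85 (adjusted p = 0.001387) and the Fc receptor FCGR3B by 6.39 ± 0.40 (adjusted p = 4.486e-05). CD14 was at the floor of 20 on every AML array and at a geometric mean of 5113 in neutrophils, at least 256-fold higher (8.0 ± 0.50). The chemokine CXCL2 went the other way, from 1866 in AML to the floor on every neutrophil array, at least 93.3-fold lower (-6.54 ± 0.82). Of the 4358 probe sets, 673 passed an adjusted p of 0.05, 379 higher and 294 lower in neutrophils. The 2 groups did not overlap in 33.7% of probe sets, where chance gives 10%.

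Further receptors and secreted proteins of mature granulocytes were among the genes with the largest differences. The decoy receptor IL1R2 was higher by 6.07 ± 0.47, the calcium-binding protein S100P by 5.74 ± 0.37, GCA by 5.91 ± 0.59 and the chemokine CXCL1 by 5.70 ± 0.64. The prostaglandin synthase gene PTGS2 was higher by 5.66 ± 0.54 and 7.20 ± 0.78 on 2 of its probe sets. Genes at the floor on every AML array included C5AR1, the receptor of complement C5a (at least 586-fold higher), the gelatinase MMP9 (at least 247-fold), S100A12 (at least 228-fold) and the transporter SLC11A1 (at least 195-fold). Another SLC11A1 probe set was higher by 2.4 and not called (adjusted p = 0.14). CXCR2 had 3 other probe sets past the filter on dim probes, none of which was called in this comparison, and 1 of them had the opposite sign (-0.14). Genes lower in neutrophils included the homeobox gene HOXB2 (-4.76 ± 0.63, adjusted p = 0.002222), the receptor AHR (-4.19 ± 0.76) and, with neutrophils at the floor, the kinases CSNK2A1 (-4.90 ± 0.34) and PKMYT1 (-4.79 ± 0.77). For ZFP36L1 the probe sets contradicted each other, with 1 lower in neutrophils (-4.54 ± 0.40, at the floor) and 1 higher by 5.43 (adjusted p = 7.424e-05). The calls of HOXB2 and AHR were lost without normalization between the arrays.

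Among gene lists fixed before the data were examined, the mature neutrophil list was higher in neutrophils by a median of 5.86 (limma camera, adjusted p = 1.09e-15, and adjusted p = 0.0346 with an estimated correlation). In it 15 of 20 genes were called, all of them higher, and 17 were higher when adjusted over the list alone. CREB5, a transcription factor gene, rose from the floor by 5.97 ± 0.32. The interferon response list had a median of 2.22 (adjusted p = 0.000172, and adjusted p = 0.547 with an estimated correlation). Of its 32 genes 5 were called, all higher, and 27 were not past the threshold, while 10 were higher when adjusted over the list alone. IRF2 was higher by 4.43 ± 0.81. Of 25 apoptosis regulators, 7 were higher, 1 was lower and 17 were not past the threshold (median 1.5, adjusted p = 0.00767, and adjusted p = 0.403 with an estimated correlation). Adjusted over the list alone, 7 were higher and 2 were lower. BCL2A1 was higher by 4.44 ± 0.55, the TNF receptor gene TNFRSF1B by 3.72 ± 0.63 and CASP5 by 3.88 ± 0.50. The 3 lists kept their direction and their calls under every scaling of the arrays that was tried, while a filter over 200 ended the call of the apoptosis regulators (adjusted p = 0.0514).

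Smaller granule and antigen lists were also higher in neutrophils, but their calls were not kept in every fit without 1 sample. In those fits the filter still asked for a value over 100 on 3 arrays. Genes past it on the 3 neutrophil arrays alone, such as CAMP and S100A12, left the lists without a neutrophil sample. The medians without a neutrophil sample are therefore not over the same genes. In the specific and gelatinase granule list, 5 of 10 genes were called, all higher, and the same number when adjusted over the list alone (median 3.11, adjusted p = 0.005655, and adjusted p = 0.341 with an estimated correlation). CAMP (at least 24.8-fold, 4.63 ± 0.37) and CEACAM1 (at least 13.6-fold, 3.77 ± 0.57) rose from the floor. The list's median fell to 1.27 without neutrophil sample 1 (adjusted p = 0.104) and 1.28 without neutrophil sample 2 (adjusted p = 0.0447), and was 2.22 without neutrophil sample 3 (adjusted p = 0.0643) and 2.09 without the 2 dimmest arrays, AML sample 2 and neutrophil sample 3, a setting chosen after the data were seen (adjusted p = 0.156). In the S100 and annexin list, 5 of 11 genes were called, all higher (median 2.14, adjusted p = 0.0067, and adjusted p = 0.409 with an estimated correlation), or 6 higher and 1 lower when adjusted over the list alone. ANXA3 was higher by 4.29 ± 0.60, and the list's median was 1.47, 1.2 and 0.96 without neutrophil samples 1, 2 and 3 (adjusted p = 0.148, 0.108 and 0.0966) and 0.77 without the 2 dimmest arrays (adjusted p = 0.276). Of 4 MHC class I genes 2 were higher, or 3 when adjusted over the list alone, with HLA-E at 3.11 ± 0.59 (list adjusted p = 0.0375, and adjusted p = 0.462 with an estimated correlation). The list's call was lost without AML sample 1 (0.0648) or AML sample 3 (0.0796), with a filter over 200 (0.0514) and with the mean of a gene's probe sets (0.127). Another HLA-E probe set was at 0.44 and not called (adjusted p = 0.618). In the monocyte list 3 of 25 genes were higher, also when adjusted over the list alone, with CYBB at 2.11 ± 0.40 (median 1.23, adjusted p = 0.00767, and adjusted p = 0.462 with an estimated correlation), and the list's median was 0.77 without AML sample 3 (adjusted p = 0.0729) and 0.64 without neutrophil sample 1 (adjusted p = 0.0295).

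Genes of translation were lower in neutrophils than in AML. Of 40 ribosomal protein genes 9 were called, all lower, and 31 were not past the threshold (median -1.02, adjusted p = 3.526e-08, and adjusted p = 0.411 with an estimated correlation), with 19 lower when adjusted over the list alone. RPL29 differed by -1.81 ± 0.36 and RPL14 by -2.85 ± 0.57. Of 20 translation factor and nucleolar genes 8 were called, all lower (median -1.14, adjusted p = 0.00251, and adjusted p = 0.403 with an estimated correlation), or 9 lower and 1 higher when adjusted over the list alone. EIF3I differed by -2.40 ± 0.37, EIF3E by -2.27 ± 0.42, NPM1 by -2.47 ± 0.41 and NCL by -1.92 ± 0.38. Both lists stayed lower under every scaling, although the calls of these 6 genes were lost without normalization. Of 42 cell cycle genes 5 were lower and 2 were higher, also when adjusted over the list alone (median -0.85, adjusted p = 0.0103, and adjusted p = 0.556 with an estimated correlation). The list's adjusted p was 0.0501 with a floor of 100 and 0.0514 with a filter over 200. CDK4 was lower by -3.01 ± 0.49 and the phosphatase gene CDC25B higher by 3.90 ± 0.60. The neutrophil arrays also differed in the GAPDH control, whose signal at the 5' end was 15.9% ± 8.19 of that at the 3' end (SD, n = 3) against 96.4% ± 22.7 in AML. An exact two-sided permutation test gave p = 0.1, the smallest p that 3 samples against 3 allow. For actin the percentages were 44.9% ± 44.0 and 82.6% ± 12.8 (SD, n = 3, exact permutation p = 0.3). Neutrophil sample 1 (89.3%) lay within the range of AML, and samples 2 (44.05%) and 3 (1.27%) lay below it.

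RNA splicing and oxidative phosphorylation lists had negative medians in neutrophils against AML, the latter not without normalization, and their calls were lost under some settings. Of 30 splicing genes 6 were called, all lower, also when adjusted over the list alone (median -0.96, adjusted p = 0.00767, and adjusted p = 0.556 with an estimated correlation). The call was lost while the median stayed negative without neutrophil sample 3 (-0.58, adjusted p = 0.0761), without normalization (-0.14, adjusted p = 0.131), and with a common trimmed mean (-0.98, adjusted p = 0.0857) or 75th percentile (-0.56, adjusted p = 0.181), and without the 2 dimmest arrays (-0.43, adjusted p = 0.129). Without AML sample 3 the median was -0.60 (adjusted p = 0.0425). Of 30 oxidative phosphorylation genes 5 were lower and 1 was higher, or 8 lower and 1 higher when adjusted over the list alone (median -0.67, adjusted p = 0.0166, and adjusted p = 0.447 with an estimated correlation). The median of that list turned to 0.24 without normalization, where the median of all probe sets was 0.34. It was -0.70 with a common trimmed mean (adjusted p = 0.0998), -0.28 with a common 75th percentile (adjusted p = 0.259), -0.64 without AML sample 1 (adjusted p = 0.0613) and -0.54 without AML sample 3 (adjusted p = 0.055). ATP5PO differed by -3.13 ± 0.48 and CYC1 rose from the floor by 4.67 ± 0.41; the call of ATP5PO was lost without normalization. The heat shock list was not called (median -0.85, adjusted p = 0.168, and adjusted p = 0.659 with an estimated correlation). Of its 16 genes 1 was higher, 5 were lower and 10 were not past the threshold, or 2 higher and 6 lower when adjusted over the list alone. HSPA6 was higher by 5.88 ± 0.62, and HSPD1 (-2.99 ± 0.42) and HSP90AB1 (-2.58 ± 0.47) were lower, calls that were lost for the latter pair without normalization.

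Several marker genes of immature cells did not pass the threshold. CD34 was at a geometric mean of 1006 in AML, and differed by -0.82 ± 0.62 in neutrophils (adjusted p = 0.401) and by -1.18 ± 0.62 in monocytes (adjusted p = 0.232). The MPO probe set tested differed by -1.22 ± 0.76 in neutrophils and -1.49 ± 0.76 in monocytes, not past the threshold (adjusted p = 0.309 and 0.221). The other MPO probe set did not pass the filter, with 89, 20 and 9738 in AML samples 1 to 3 and at most 149 in the mature samples. The 3 probe sets of ELANE were lower in both mature groups, by -1.06 to -3.83 in neutrophils and by -1.35 to -4.75 in monocytes, and none was called. For MYB, 1 probe set was lower in neutrophils (-4.49 ± 0.89, adjusted p = 0.0124) and in monocytes (-3.66 ± 0.89, adjusted p = 0.0277), while the other had the opposite sign and no call (1.75 and 1.87). The called MYB probe set had an adjusted p of 0.0528 in neutrophils without neutrophil sample 2, and from 0.0715 to 0.11 in monocytes without AML sample 2, AML sample 3, monocyte sample 2 or monocyte sample 3. KIT, FLT3, LTF and CEBPA did not pass the filter on dim probe sets, and NCF1 had no probe set of its own. SPI1 was higher in neutrophils by 4.58 ± 1.23 (adjusted p = 0.0385), with an adjusted p from 0.0504 to 0.108 without AML sample 3, without any of the 3 neutrophil samples, and without monocyte sample 2 or 3.

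The split between higher and lower calls in this comparison moved with the scaling: without normalization 173 probe sets passed (165 higher, 8 lower), and with the arrays scaled to a common trimmed mean 828 passed (291 higher, 537 lower), as the median of all probe sets moved from -0.18 to 0.34 and -0.57. The count was 242 without neutrophil sample 2 (118 higher, 124 lower) and 394 without AML sample 3 (275 higher, 119 lower), it was 504 without AML sample 1 (322 higher, 182 lower), and lower calls also outnumbered higher ones without neutrophil sample 1 (198 higher, 254 lower) and neutrophil sample 3 (265 higher, 271 lower).

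**Figure D2:**
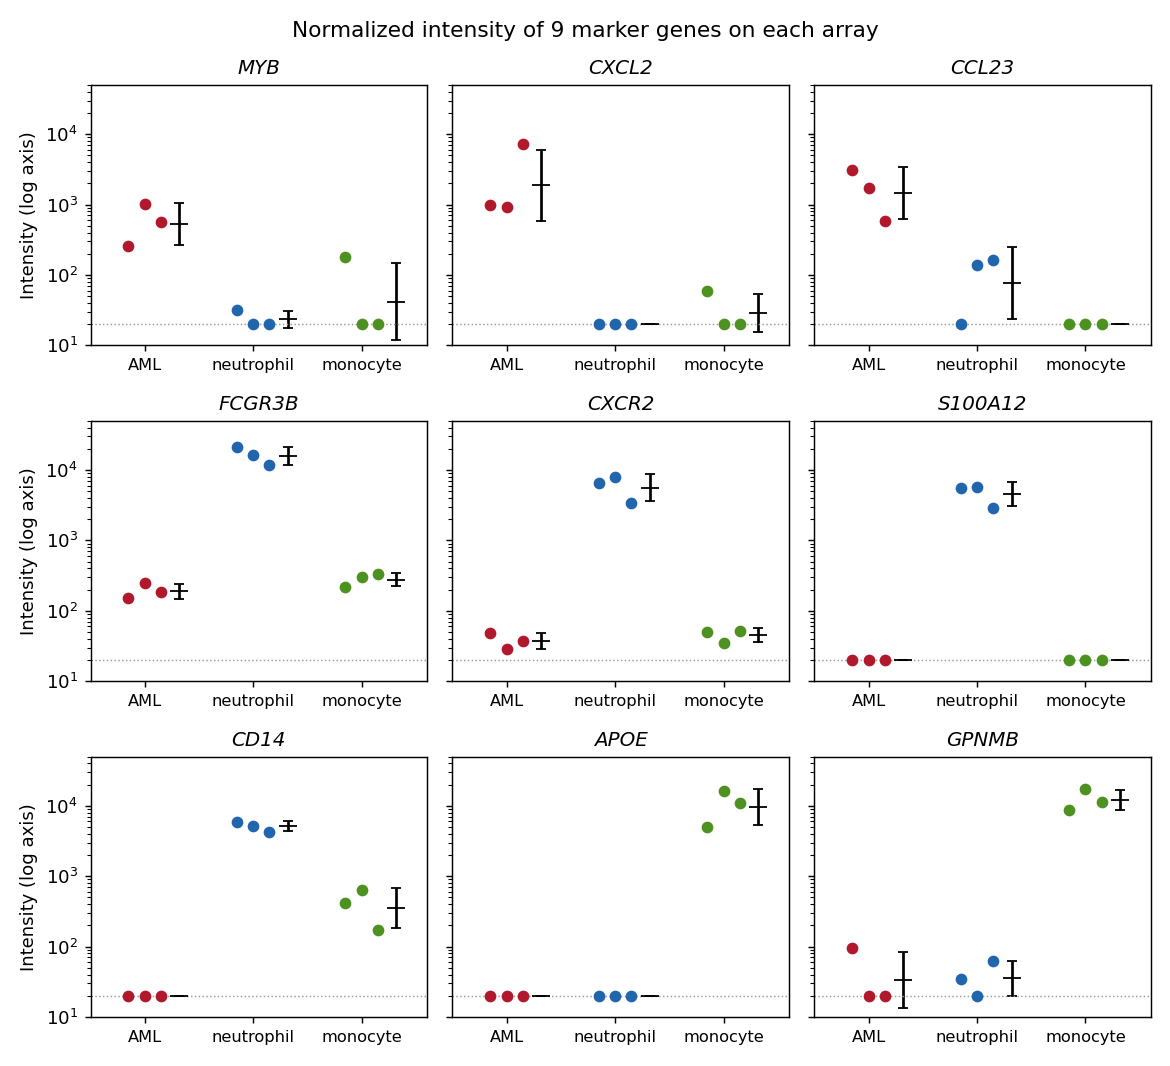
Normalized intensity (log axis) of 9 marker genes on each array (points), with the group's mean and SD of log2 values beside them (bars) and the floor of 20 as a dotted line. CD14 lay at the floor in AML and at geometric means of 5113 in neutrophils and 355 in monocytes; MYB is drawn for the probe set that was called, while its other probe set had the opposite sign.

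The second comparison set monocytes against AML blasts and asked the same of the monocytic branch. Apolipoprotein E (APOE) was at the floor on every AML array and at a geometric mean of 9655 in monocytes, at least 483-fold higher (8.91 ± 0.46, adjusted p = 2.08e-05). The chitinase-like gene CHI3L1 was higher by 9.45 ± 0.43 (adjusted p = 2.08e-05), the fatty acid-binding protein gene FABP4 by 6.83 ± 1.25 (adjusted p = 0.00928) and the osteopontin gene SPP1 by 7.68 ± 0.54 (adjusted p = 7.911e-05). CD14 was at least 17.8-fold higher than in AML (4.15 ± 0.50, adjusted p = 0.0013). The chemokine gene CCL23 fell from 1460 in AML to the floor on every monocyte array (-6.19 ± 0.88, adjusted p = 0.00286). In all 617 probe sets passed, 346 higher and 271 lower in monocytes. The 2 groups did not overlap in 40.6% of probe sets, where chance gives 10%.

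Further genes differed strongly between monocytes and AML. The sterol hydroxylase gene CYP27A1 was at least 505-fold higher than the floor in AML, MMP9 at least 368-fold, GDF15 at least 177-fold and C5AR1 at least 139-fold. The lysosomal lipase gene LIPA was higher by 5.11 ± 0.51 (adjusted p = 0.000606), A2M by 5.88 ± 0.89, FBP1 by 4.88 ± 0.80 and the chitinase gene CHIT1 by 4.87 ± 0.85. GM2A (6.53 ± 1.32) and LPL (5.70 ± 1.08) were also higher, with an adjusted p of 0.0541 and 0.0532 without monocyte sample 2 and of 0.0536 and 0.0512 without monocyte sample 3. CYBB, a subunit of the NADPH oxidase, was higher by 3.58 ± 0.40 and the interleukin-1 receptor antagonist gene IL1RN by 3.08 ± 0.57 (adjusted p = 0.00968). EIF2S1 rose from the floor by 5.58 ± 0.32 and FADD by 4.36 ± 0.77. Genes lower in monocytes included NEFL (-4.70 ± 0.77), NUCB2 (-4.07 ± 0.71), SPIB (-3.99 ± 0.61) and CYP2F1 (-4.61 ± 0.55, at the floor in monocytes). Another NEFL probe set differed by -0.59 and was not called (adjusted p = 0.391). The calls of NUCB2 and SPIB were lost without normalization.

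Immediate early genes were lower in monocytes than in AML under every scaling. Of 28 such genes 13 were lower, 2 were higher and 13 were not past the threshold (median -1.84, adjusted p = 0.000666, and adjusted p = 0.403 with an estimated correlation), or 15 lower and 3 higher when adjusted over the list alone. DUSP1 differed by -3.44 ± 0.48, MCL1 by -2.86 ± 0.38, FOSB by -3.57 ± 0.54 and KLF10 by -2.18 ± 0.38, and these calls were lost without normalization. Proteasome genes were higher, with 4 of 22 called, all higher (median 1.14, adjusted p = 0.0001746, and adjusted p = 0.403 with an estimated correlation), or 9 higher when adjusted over the list alone. Oxidative phosphorylation genes had 5 of 30 higher and 1 lower, also when adjusted over the list alone (median 0.64, adjusted p = 0.0375, and adjusted p = 0.462 with an estimated correlation), and the list's adjusted p was 0.0587 without AML sample 2 (median 0.42), 0.0506 without neutrophil sample 2 and 0.0514 with a filter over 200. CYC1 rose from the floor by 5.57 ± 0.41.

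Genes of progenitors and of the red cell lineage were lower in monocytes than in AML under every scaling. Both calls were lost without the 2 dimmest arrays (progenitor median -1.13, adjusted p = 0.11; erythroid median -1.11, adjusted p = 0.0515), and that of the progenitor list with a filter over 200 (-1.17, adjusted p = 0.0514). Of 16 progenitor genes 3 were called, all lower (median -1.52, adjusted p = 0.0122, and adjusted p = 0.403 with an estimated correlation), or 5 lower when adjusted over the list alone. Of 17 erythroid genes 6 were called, all lower (median -1.2, adjusted p = 0.005655, and adjusted p = 0.409 with an estimated correlation), or 8 lower when adjusted over the list alone. SLC4A1 differed by -6.06 ± 0.70 and the hemoglobin gene HBD by -4.53 ± 0.79, the latter not called without normalization. Of 12 platelet genes 3 were lower and 2 were higher, or 7 lower and 2 higher when adjusted over the list alone (median -2.40, adjusted p = 0.0358, and adjusted p = 0.403 with an estimated correlation). ITGA2B (at least 19.6-fold lower, -4.30 ± 0.36) and PPBP (at least 30.7-fold lower, -4.94 ± 0.82) were at the floor on every monocyte array, and TBXAS1 was higher by 4.13 ± 0.57. The platelet list's adjusted p was between 0.0641 and 0.0955 without AML sample 1, AML sample 3, neutrophil sample 1, neutrophil sample 3 or monocyte sample 1. Without the filter on dim probe sets its median shrank to -0.25 (adjusted p = 0.136), with floors of 50 and 100 to -1.72 and -1.05 (adjusted p = 0.0846 and 0.193), and the call was also lost with a filter over 200 (-2.44, adjusted p = 0.0992) and a common trimmed mean (-3.12, adjusted p = 0.0551). Of 40 ribosomal protein genes limma called 0, and 10 had an unadjusted p under 0.05 (list median -0.63, adjusted p = 0.0001101, and adjusted p = 0.488 with an estimated correlation). Without normalization their median turned to 0.37, still below the median of all probe sets in that setting (1.14). Splicing genes had 3 of 30 lower and 1 higher, also when adjusted over the list alone (median -0.57, adjusted p = 0.0375, and adjusted p = 0.628 with an estimated correlation). The median of the splicing genes turned to 1.12 without normalization, close to the 1.14 of all probe sets. It was -0.05 with a common 75th percentile (adjusted p = 0.459) and -0.42 with a common trimmed mean (adjusted p = 0.247). The adjusted p was from 0.0581 to 0.143 without AML sample 3, neutrophil sample 1, monocyte sample 2 or monocyte sample 3.

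The split between higher and lower calls again moved with the scaling: 450 probe sets passed without normalization (416 higher, 34 lower) and 662 with a common trimmed mean (254 higher, 408 lower), as the median of all probe sets moved from -0.06 to 1.14 and -0.46. Counts without single samples were 395 without AML sample 3 (248 higher, 147 lower) and 292 (156 higher, 136 lower), 205 (93 higher, 112 lower) and 202 (104 higher, 98 lower) without monocyte samples 1, 2 and 3.

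The 2 comparisons against AML were then intersected, since a gene that moved alike in both mature cell types may be a gene of the difference between blasts and mature cells. MMP9 was higher by 7.95 ± 0.50 in neutrophils and 8.52 ± 0.50 in monocytes, and C5AR1 by 9.19 ± 0.39 and 7.12 ± 0.39, each from the floor in AML. The proton pump gene ATP6V0D1 was higher by 6.10 ± 0.47 and 6.0 ± 0.47, and the chemokine receptor gene CCR1 by 5.58 ± 0.71 and 5.33 ± 0.71. Another CCR1 probe set was higher by 1.95 and 2.83 and called in neither comparison (adjusted p = 0.341 and 0.176). CXCL2 was lower by -6.54 ± 0.82 and -6.01 ± 0.82, and NME4 by -5.10 ± 0.84 and -5.33 ± 0.84, the neutrophil call of NME4 being lost without normalization. In all 167 probe sets passed in both comparisons with the same sign, 104 higher and 63 lower in the mature cells, and 17 passed with opposite signs. Further genes from the floor in AML were CYP27A1 (6.24 ± 0.62 and 8.98 ± 0.62), MGAT1 (5.31 ± 0.39 and 6.99 ± 0.39) and RAB31 (6.79 ± 0.35 and 4.85 ± 0.35). CXCL3 was lower by -4.30 ± 0.77 and -4.55 ± 0.77 and EYA3 by -3.31 ± 0.46 in each, with CXCL3 at the floor in monocytes and EYA3 in both mature groups, and both genes lost their calls with a floor of 100. CDC25B and BCL2A1 were higher in both mature groups, by 3.90 ± 0.60 and 4.44 ± 0.55 in neutrophils and by 3.78 ± 0.60 and 3.50 ± 0.55 in monocytes.

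Both comparisons used the same AML arrays, so part of the overlap may come from the shared controls. Unchanged groups simulated against such controls shared a mean of 0.01 probe sets, at most 1 in 100 simulations. With no true difference few probe sets pass in either comparison, so this count was bound to be small. It cannot tell how much the shared arrays add where many probe sets differ. Independent lists of the observed lengths would share 30.1 higher and 18.3 lower probe sets, a figure that leaves the shared AML arrays out of account. Across probe sets the log2 differences of the 2 comparisons correlated with r = 0.369, where unchanged groups gave 0.50. Their covariance was 1.15 against 0.347 in the simulation, a difference of 0.805. Without normalization 57 probe sets were shared (54 higher, 3 lower), and with a common trimmed mean 193 (69 higher, 124 lower). Without AML samples 1, 2 and 3 the count was 163 (39 of them lower), 134 (33 lower) and 98 (84 higher, 14 lower). It was 119 (75 higher, 44 lower) without neutrophil sample 1 and 93 (57 higher, 36 lower) without neutrophil sample 2, and 104 (68 higher, 36 lower), 75 (46 higher, 29 lower) and 80 (53 higher, 27 lower) without monocyte samples 1, 2 and 3.

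The third comparison set the mature cell types against each other. The glycoprotein gene GPNMB was higher in monocytes, with a neutrophil minus monocyte difference of -8.41 ± 0.71 (adjusted p = 0.0001685). CXCR2 was higher in neutrophils by 6.95 ± 0.44 (adjusted p = 4.126e-05) and S100P by 6.48 ± 0.37 (adjusted p = 2.172e-05). Of the other CXCR2 probe sets, 1 was also called (4.15 ± 0.73) and 1 had the opposite sign without a call (-1.34). APOE was at the floor on every neutrophil array, at least 483-fold lower than in monocytes (-8.91 ± 0.46). CD14, widely used as a monocyte surface marker, was higher in the neutrophil samples by 3.85 ± 0.50 (adjusted p = 0.00126). In all 947 probe sets passed, 436 higher and 511 lower in neutrophils. The 2 groups did not overlap in 47.2% of probe sets, where chance gives 10%.

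Genes higher in neutrophils included the chemokine receptor genes CXCR1 (5.98 ± 0.76) and CXCR4 (6.30 ± 1.07), the adhesion molecule gene ICAM3 (6.42 ± 0.97), the chemokine gene CXCL1 (6.60 ± 0.64) and the transporter gene SLC11A1 (5.88 ± 0.86). Another SLC11A1 probe set was higher by 2.94 and not called (adjusted p = 0.0679). With monocytes at the floor on all arrays, S100A12 was at least 228-fold higher, PTGS2 at least 207-fold, the retinoic acid receptor gene RARA at least 202-fold, the properdin gene CFP at least 198-fold and HAL at least 120-fold. VCAN, also at the floor on every monocyte array, was at least 94.0-fold higher. S100A8 and AIF1 were higher in neutrophils by 5.17 ± 0.72 and 4.34 ± 0.55. Genes higher in monocytes included the lipid droplet gene PLIN2 (-7.25 ± 0.94), FABP5 (-6.91 ± 0.85), GM2A (-6.57 ± 1.32), the cathepsin gene CTSL (-6.21 ± 1.23), ANXA2 (-6.15 ± 1.2) and SPP1 (-5.94 ± 0.54). LIPA (at least 498-fold lower in neutrophils on 1 of its probe sets, -8.96 ± 0.51), FN1 (-7.02 ± 0.94), CHIT1 (-6.98 ± 0.85) and the nuclear receptor gene NR1H3 (-6.69 ± 0.33) were at the floor in neutrophils. HLA-DRA (-1.11 ± 0.71), CSF1R (-1.70 ± 1.36) and SPI1 (2.28 ± 1.23) were not past the threshold (adjusted p = 0.298, 0.409 and 0.214).

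The monocyte list was not called between the mature types (6 of 25 higher and 2 lower, or 6 and 4 when adjusted over the list alone; median 0.22, adjusted p = 0.366, and adjusted p = 0.730 with an estimated correlation) or in monocytes against AML (5 of 25 higher and 1 lower, or 5 and 2 over the list alone; median 0.77, adjusted p = 0.160, and adjusted p = 0.671 with an estimated correlation). The mature neutrophil list was higher in neutrophils by a median of 4.74 and kept that sign under each scaling (adjusted p = 1.162e-12, and adjusted p = 0.0346 with an estimated correlation). In it 16 of 20 genes were called, all higher, and 17 were higher when adjusted over the list alone. Immediate early genes were higher in neutrophils, with 12 of 28 higher and 4 lower, also when adjusted over the list alone (median 1.56, adjusted p = 0.00794, and adjusted p = 0.403 with an estimated correlation). DUSP1 was higher by 4.99 ± 0.48, MCL1 by 3.95 ± 0.38 and IER2 by 3.62 ± 0.40. Myeloid transcription factors had 6 of 29 higher and 1 lower, or 7 and 2 when adjusted over the list alone (median 1.0, adjusted p = 0.0132, and adjusted p = 0.403 with an estimated correlation). MXD1 rose by 5.17 ± 0.68 and RXRA by 3.89 ± 0.42 from the floor in monocytes, and the list's adjusted p was 0.104 without neutrophil sample 1 and 0.0943 without neutrophil sample 2. Platelet genes were higher in neutrophils under every scaling, with 5 of 12 higher and 1 lower, or 7 and 1 when adjusted over the list alone (median 1.63, adjusted p = 0.00606, and adjusted p = 0.403 with an estimated correlation). PF4 differed by 5.99 ± 0.91, PPBP by 5.54 ± 0.82 and ITGA2B by 4.81 ± 0.36, the latter genes from the floor in monocytes. S100 and annexin genes had 6 of 11 higher and 2 lower, also when adjusted over the list alone (median 1.86, adjusted p = 0.0489, and adjusted p = 0.488 with an estimated correlation), and the adjusted p was from 0.061 to 0.403 without any 1 of the AML or neutrophil samples or monocyte sample 1. That list's median fell to 0.278, 0.133 and 0.145 without neutrophil samples 1, 2 and 3 and to 0.14 without the 2 dimmest arrays, and its call was also lost with a common trimmed mean (adjusted p = 0.0736), a common 75th percentile (0.0769), the replicate block (0.0704), a floor of 100 (0.0501), no filter (0.0547), a filter over 200 (0.0514) and the mean of a gene's probe sets (0.0571). Without a neutrophil sample S100A12 no longer passed the filter and left the S100 and annexin list, so these medians are not over the same genes. T and NK cell genes had 1 of 26 higher and 1 lower, or 1 higher when adjusted over the list alone (median 1.02, adjusted p = 0.0489, and adjusted p = 0.659 with an estimated correlation), with an adjusted p from 0.0729 to 0.143 without AML sample 3, neutrophil sample 1, monocyte sample 2 or monocyte sample 3. Its median was 1.66 without neutrophil sample 3 and 1.95, 0.62 and 0.64 without monocyte samples 1, 2 and 3, and its call was also lost with a common trimmed mean (adjusted p = 0.0677), a common 75th percentile (0.0688), no filter (0.0666) and the mean of a gene's probe sets (0.0556). The eosinophil and basophil gene CLC was higher by 6.08 ± 1.27, and LTB, a lymphocyte gene, by 5.45 ± 1.18, with an adjusted p of 0.0519 for LTB without monocyte sample 3.

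Proteasome and oxidative phosphorylation genes were lower in neutrophils than in monocytes under every scaling. Of 22 proteasome genes 10 were called, all lower (median -1.93, adjusted p = 0.0001193, and adjusted p = 0.403 with an estimated correlation), or 16 lower when adjusted over the list alone. PSMC2 differed by -6.01 ± 0.65 and PSMB5 by -2.10 ± 0.32. Of 30 oxidative phosphorylation genes 9 were called, all lower (median -1.21, adjusted p = 2.546e-05, and adjusted p = 0.403 with an estimated correlation), or 17 lower when adjusted over the list alone. CYCS differed by -2.92 ± 0.48 and ATP5MC3 by -3.85 ± 0.83. Of 42 cell cycle genes 9 were called, all lower, also when adjusted over the list alone (median -0.96, adjusted p = 0.0103, and adjusted p = 0.556 with an estimated correlation), with PCNA at -5.53 ± 0.91 and CDK4 at -4.12 ± 0.49, and the list's median shrank to -0.27 without monocyte sample 1 (adjusted p = 0.232), and its adjusted p was 0.0605 with a filter over 200. Of 20 translation genes 7 were lower and 2 were higher, or 8 and 2 when adjusted over the list alone (median -1.29, adjusted p = 0.00767, and adjusted p = 0.403 with an estimated correlation), and without normalization the list's adjusted p was 0.0854. Of 16 heat shock genes 5 were lower and 2 were higher, or 8 and 2 when adjusted over the list alone, and the list was not called (median -1.25, adjusted p = 0.0951, and adjusted p = 0.595 with an estimated correlation). HSPB1 (-6.50 ± 1.08, at the floor in neutrophils), HSPD1 (-3.07 ± 0.42) and HSPE1 (-2.94 ± 0.50) were lower in neutrophils. Control signal of GAPDH at the 5' end was 15.9% ± 8.19 of the 3' end in neutrophils and 110% ± 11.7 in monocytes (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), and that of actin 44.9% ± 44.0 and 93.8% ± 16.5 (exact p = 0.2).

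Without normalization 449 probe sets passed in this comparison (135 higher, 314 lower), with the median of all probe sets at -0.72 against -0.04. The count was 551 without neutrophil sample 2 (228 higher, 323 lower). Without any 1 monocyte sample the higher calls outnumbered the lower ones, with counts of 600 (330 higher, 270 lower), 491 (295 higher, 196 lower) and 464 (257 higher, 207 lower) without monocyte samples 1, 2 and 3.

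**Figure D3:**
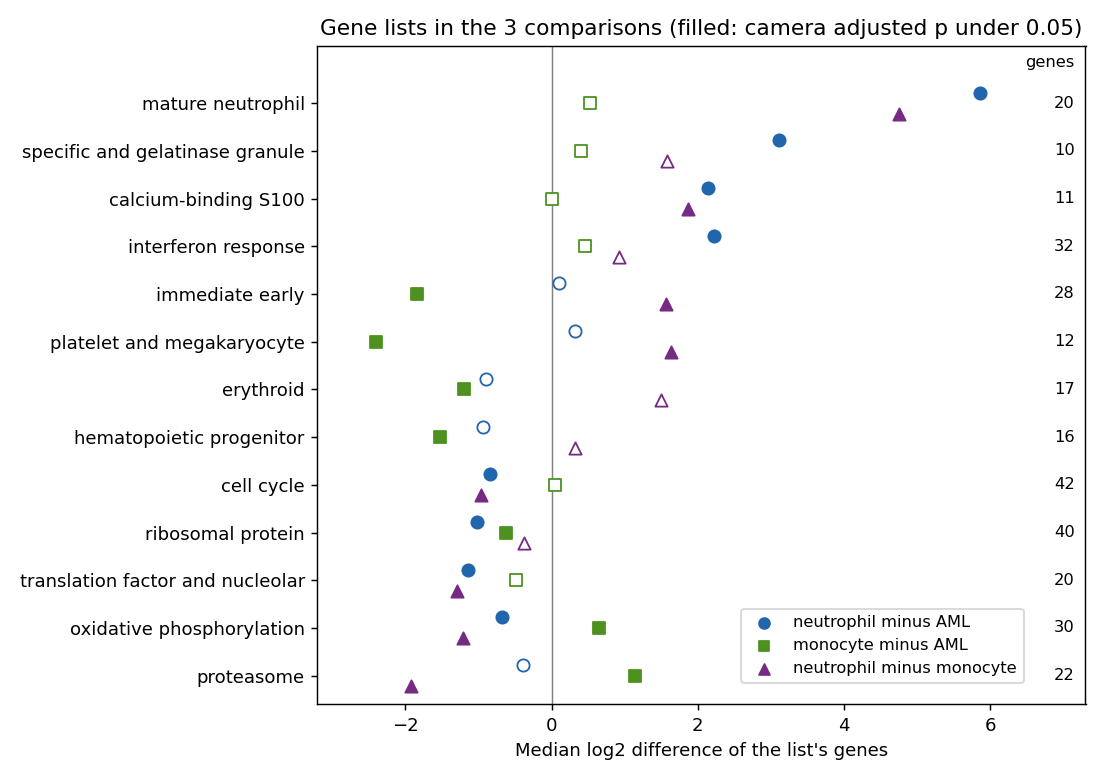
Median log2 difference of the genes of 13 lists in the 3 comparisons (1 symbol per comparison, filled where limma camera with a preset correlation gave an adjusted p under 0.05), with the number of genes tested at the right. The mature neutrophil list had medians of 5.86 against AML and 4.74 against monocytes. The medians of ribosomal protein genes (monocyte minus AML) and of oxidative phosphorylation genes (neutrophil minus AML) changed sign without normalization. Both stayed below the median of all probe sets in that setting (1.14 and 0.34).

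Over the 3 comparisons, 30 of 81 list tests passed with the preset correlation and 2 with an estimated correlation, both of the mature neutrophil list. Of the calls of genes named by the rule, 71 of 125 in neutrophils against AML, 48 of 106 in monocytes against AML and 94 of 114 in neutrophils against monocytes were kept in each fit without 1 sample that tested them. Probe sets that no longer passed the filter in such a fit were not counted as lost. Per sample left out, 8 to 30 of the 345 calls were not tested. Without normalization but in no other setting tried, 18, 10 and 14 of these calls were lost, among them CDK4 and CYBB in neutrophils against AML and PSMB5 in neutrophils against monocytes.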

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

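The differences in this part were tested by the planned comparison of neutrophils with monocytes. The fits without single samples were planned too, while counting these probe sets over them was chosen after the result was seen.

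In 17 probe sets the 2 mature cell types differed from AML in opposite directions, each past the threshold, and the planned test of the difference between neutrophils and monocytes called all 17 (highest adjusted p 0.00161), which opposite calls against the same AML arrays make nearly certain. Neutrophil minus monocyte differences were positive for 8: RARA (7.66), CFP (7.63), ALOX5 (5.86), JUNB (3.68), IER2 (3.62), LYL1 (3.59), MME (3.26) and LYN (3.12). They were negative for 9: LIPA (-8.96), PSMC2 (-6.01), IDH1 (-5.08), PSMD14 (-4.65), AZIN1 (-4.52), MGLL (-4.28), PRDX1 (-4.08), IARS1 (-3.91) and CD81 (-3.43). RARA, CFP and LYL1 were at the floor in monocytes and LIPA and AZIN1 in neutrophils, so their differences are bounds. Another probe set of JUNB had the opposite sign in neutrophils against AML (-1.41, not called). Both calls against AML were kept in each fit without 1 sample for 1 of the 17 probe sets, LIPA. Without normalization the calls of MME and LYN between the mature types were lost, and their differences between monocytes and AML changed sign (0.14 and 0.32). No explanation was tested for these genes.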

How the results depend on the processing

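Leaving out the 2 dimmest arrays was chosen after the data were seen; the other alternatives were planned. The counts of probe sets were 673 in neutrophils against AML, 617 in monocytes against AML, 947 between the mature types and 167 shared by both comparisons against AML. Without normalization 173, 449 and 57 passed in the first, the third and the shared set. With array quality weights the 4 counts were 1021, 935, 1873 and 308. With only the groups compared in the fit, neutrophils against AML gave 339 and the shared set 89. The cause was not tested. Without 1 sample, the counts ranged from 242 to 588, from 202 to 797, from 464 to 1069 and from 75 to 201. The other alternatives stayed within 1.5 times of these counts, and without the 2 dimmest arrays the counts were 607, 748, 1003 and 203. A minimum of 2-fold removed no call. No probe set called in both a setting and the fit reported here had opposite signs in them.

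Deviations of samples with the same replicate number correlated from -0.11 to 0.06 across probe sets. Between neutrophils and monocytes these values were all positive (0.033 to 0.064). Samples with different numbers were not compared, so this cannot tell whether the numbers mark a shared donor. With the number as a replicate block, the counts were 466, 482, 789 and 124.

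Of 345 calls of named genes, 192 were kept without normalization, 320 with a common trimmed mean, 322 with a common 75th percentile, 280 without the filter on dim probe sets, 281 with only the groups compared and 295 with the replicate block. Without normalization 4 calls in monocytes against AML changed sign: LYN (0.32), MME (0.14), SERPINB1 (0.091) and 1 probe set of SF1 (0.24), and the cause was not tested. That setting raised the median of all probe sets in that comparison to 1.14. Of 30 list calls, 2 were kept with an estimated correlation, both of the mature neutrophil list, and 22 to 29 with the other settings. Signal over background limits the dim probe sets: a floor of 100 kept 320 of the named calls, and differences from the floor are bounds.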

Other observations

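The tests of explanations for the 3 patterns below were chosen after the results were seen, as were the macrophage and circulating monocyte lists of the first pair of patterns. The tests of the lists fixed earlier and the counts over other splits of the samples were planned.

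With 3 samples against 3 there are 10 splits, too few for a share under 0.05. In neutrophils against AML 1 of the 10 splits gave as many probe sets as the real 673, and the highest other split gave 7. In monocytes against AML it was 1 of 10, with 617 against 2, and between the mature types 1 of 10, with 947 against 0 called by limma. For the 167 probe sets shared by both comparisons against AML, 3 of 100 splits of the 9 samples into 3 groups gave as many, the real one included. That share is under 0.05. The highest of the others, 300, kept the same 3 groups with another cell type as the reference, and the highest among other groupings was 171, above the real count. A low share shows that the samples form groups. It cannot tell whether the sharing against AML in particular exceeds chance.

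Macrophage-type genes were high in the monocyte samples. Of 37 genes of a macrophage and lysosomal lipid list, 23 were called against AML, all higher (median 3.95), with CHI3L1, GPNMB and APOE at geometric means of 14640, 12030 and 9655; lists fixed earlier hold 10 of its 46 genes. Against an effect of the normalization as the whole cause, at least 21 of the 23 calls were kept under each other scaling. Neutrophils mixed into these samples could raise a gene at most to its level in neutrophils. Against such mixing, all 23 were higher than in the neutrophil samples (lower quartile 2.88, 20 called). The list was written after its values had been seen, and the 23 genes were already called high in monocytes. That choice favours both results, which speak only for these genes. A batch of the monocyte arrays stays open and cannot be told apart from the group, since 11 of 33 control probes of bacterial and phage genes separated all monocyte arrays from the others, against 2 for the AML arrays and 2 for the neutrophil arrays (chance gives 2.38% of probes). Maturation toward macrophages before RNA extraction may be another cause: genes of the circulating monocyte list had a median of -0.77 against AML (2 of 14 called higher and 3 lower), but that list was written after its values had been seen, and the monocyte list fixed earlier had a positive median and was not called (0.77, 5 of 25 higher and 1 lower, adjusted p = 0.160), so this stays open.

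Genes of a circulating monocyte list written after the values had been seen were higher in the neutrophil samples than in the monocyte samples, whereas the monocyte list fixed earlier was not called (6 of 25 higher, 2 lower and 17 not past the threshold, median 0.22, adjusted p = 0.366). Of 14 genes of the later list 11 were called, all higher in neutrophils (median 4.09), among them S100A8 and CD14 at geometric means of 8469 and 5113. Of the 16 listed, the mature neutrophil list fixed earlier holds 4 and the monocyte list 7. Without the members of that mature neutrophil list 8 of 11 were called (median 3.85). The genes left still include S100A8, a member of the S100 and annexin list, so this count does not remove every gene that neutrophils may express. At least 10 of the 11 calls were kept under each other scaling, and 0 samples labelled monocyte had a mature neutrophil median at or above the lowest sample labelled neutrophil, which argues against an exchange between these groups. Mononuclear cells left in the neutrophil samples in different amounts could add to the pattern: relative to mature neutrophil genes, the list's median was 0.40 higher in neutrophil sample 1 than in sample 2, within the spread of its genes, while HLA class II genes differed by 1.35. In the same direction, the monocyte list fixed earlier differed by 0.805, T and NK cell genes by 0.589, platelet genes by 0.502 and B cell genes by 0.37. Expression of these genes by neutrophils themselves was not tested and stays open.

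Ribosomal protein and translation lists were lower in the neutrophil samples than in AML with a preset correlation (9 of 40 and 8 of 20 genes called, all lower, 31 and 12 not past the threshold), and not called with an estimated one (adjusted p = 0.411 and 0.403). Without neutrophil sample 3, at least 79.3% of each list's median difference was kept, which argues against degraded RNA in that sample as the whole cause. Without normalization the lists' medians lay at -0.93 and -0.89 relative to the median of all probe sets, with upper quartiles of -0.64 and -0.26, which argues against quantile normalization as the source, while a change made before deposit was not tested. Loss of signal toward the 5' end in all neutrophil samples stays open and cannot be told apart from the cell type. The highest GAPDH percentage in neutrophils lay 47.2 points below the lowest of the other samples. Actin in neutrophil samples 2 (44.05%) and 3 (1.27%) also lay below the lowest of AML (68.0%) and of monocytes (76.3%). Only actin in neutrophil sample 1 (89.3%) lay within the range of AML (68.0% to 92.2%). A lower share of translation RNA in mature neutrophils, which divide no more, may also contribute, and was not tested apart from such a loss.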
